A study of Mus musculus with 8 samples.

How the data were processed

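RNA was measured in the hippocampus of 8 male C57BL/6J mice, 4 whose mothers ate a control diet and 4 whose mothers ate the same low-phytoestrogen diet with 50 mg of bisphenol A (BPA, a plasticiser monomer that can act on hormone receptors) per kg, during pregnancy and lactation. All pups were moved to control diet at weaning on postnatal day 21 and were sampled at 20 weeks, per the labels. Polyadenylated RNA was selected and made into stranded libraries (ScriptSeq v2), which were sequenced on a NextSeq.

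The deposited table holds raw read counts per gene symbol, 24527 rows by 8 libraries, in whole numbers that are not normalized. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.3.0e and featureCounts 1.5.0 were used with the mm10 build, and DESeq2 is also named, without a version. Per the file headers, genes follow the refGene annotation. The strand setting of the counting is not given in the sources used here, so values of genes that overlap another gene on the opposite strand are uncertain. Beside those marked in the results, named genes with such an overlap are Mt2, Npnt, Fdft1, Cdh24, Ermn, Folr1, Pou3f1, Man1a, Dnajb11, Thra, Thrb, Paqr5, Olig1, Vcan, Chrm3, Snap25, Nrn1, Neurod1, Nkx2-1, Six3, Slc6a13 and Cux2. The recorded overlaps of Erbb4 and Htr2c are incomplete, so an overlap on the opposite strand may be missed. Overlaps of Lrp1, Malat1, Meg3, Ttr and Enpp2 are not given. Each column was matched to a sample by the library code in its title. The series text calls the 4 animals of a group independent biological replicates. Whether they came from separate litters is not given in the sources used here; if littermates were used, the p-values measure the spread between these animals only.

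Library totals were 27.1 to 40.8 M (mega) counts in controls and 43.1 to 54.01 M in BPA mice. Genes with too few counts were removed with filterByExpr of edgeR, which left 15434 genes and 3750 rows had no read in any library. Replicates of a group differed beyond sampling noise in all 12 pairs (chi-square per degree of freedom 10.9 to 26.4), so none was counted as a duplicate. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, 1 group term, a two-sided p and Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the test statistic. Expression levels are given as CPM with TMM scaling, as mean ± SD over 4 mice, and log2 fold changes as estimate ± SE. The biological coefficient of variation was 8.20%, the median SE of a log2 fold change was 0.0746, and for 85.4% of genes the 95% interval of the fold change lay inside 1.5-fold in both directions.

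Tested on simulated counts for the same 15434 genes, with 50 genes changed at each size, edgeR recovered 38% at 1.25-fold, 66% at 1.5-fold, 90% at 2-fold and 98% at 3-fold, with 11 false calls; DESeq2 recovered 40%, 66%, 92% and 94%, with 15 false calls. Genes of every size were changed together in the same simulated counts, and the adjusted threshold is stricter where fewer genes change. The recovered shares therefore hold for that number of changed genes and may be lower where few genes change. A simulated list of 20 genes moved 1.25-fold was called by the list test and 0 of 30 unmoved lists were called. The simulated genes were drawn independently, so this does not show how often lists of genes that vary together are called falsely.

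Before the data were examined, 20 gene lists for pathways, 19 lists of cell type and regional markers, and 28 single genes were fixed. Lists with at least 5 tested genes were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over the 38 lists tested; the blood marker list had 4 tested members and was not tested. Camera was repeated with an estimated correlation, and fry was run for directional and mixed change. A list score is the mean log2 CPM of the members in a library, compared between groups by a two-sided exact permutation test whose smallest p is 0.02857.

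Genes were named by a rule fixed in advance: every gene past the threshold if 30 or fewer passed, and, as none did, the 20 with the smallest unadjusted p, given by value; in each list the members past the threshold over all genes and over the list alone, at most 4, or the 2 with the smallest p; and the 28 fixed genes. Predicted genes with Gm or Rik symbols are counted and not named. Results of some genes chosen by this rule are not reported here, though they stay in every test, list and count of genes tested. Genes outside this rule, named after their values were seen, are Gm20219, Lrp1, Malat1 and Meg3, which DESeq2 called, and Ttr and Enpp2, members of the choroid plexus list. Rn45s, also outside this rule, is given as a share of library counts. Gene positions, GC content and length come from the GENCODE annotation of the mm10 assembly, and 97.5% of tested genes had a GC content and length.

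Other settings fixed in advance were DESeq2 size factors, upper-quartile factors, library totals only, no filter on low counts, a filter of CPM over 1 in 4 libraries, each library left out, a replicate block, DESeq2 1.42.0, limma-voom with quality weights, robust empirical Bayes, 1 surrogate variable (sva 3.50.0) and a threshold of 0.10. After the data were examined, these were added: log2 library total as a covariate, counts thinned to the smallest total (1 draw for the tests and the mean of 20 draws for scores), offsets for GC content and length, the choroid plexus score as a covariate, and leaving out Rn45s or the library with the highest choroid plexus score in each group. All 8 libraries entered every comparison unless a setting says otherwise.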

Results

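Hippocampal RNA was compared between 4 adult male mice exposed to BPA through their mothers and 4 control males. BPA libraries were deeper: totals were 46.2 ± 5.24 M counts against 33.8 ± 5.96 M in controls (mean ± SD, n = 4 each). Every BPA library exceeded every control library, from 43.1 to 54.01 M against 27.1 to 40.8 M (two-sided exact permutation p = 0.02857, the smallest that 4 against 4 can give). Exposure and depth therefore cannot be separated by group. Rn45s, the 45S ribosomal RNA precursor, held 6.58 ± 1.14% of counts in controls and 6.33 ± 0.97% in BPA mice (n = 4 each; exact permutation p = 0.7714). The comparison addressed which hippocampal transcripts differ in adulthood after exposure that ended at weaning, in a study concerned with neurotransmitters and neuroactive steroids.

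Among the genes with the smallest p, most were lower in BPA mice. Ahdc1 (chromosome 4, 133011260 to 133078110) was at 159 ± 28.7 CPM in controls and 95.6 ± 12.04 CPM in BPA mice, a log2 fold change of -0.74 ± 0.12. Grik5, which encodes a kainate receptor subunit (chromosome 7, 25009849 to 25072346), was at 677 ± 235 CPM in controls and 307 ± 62.4 CPM in BPA mice (-1.14 ± 0.21), and Slc1a2, the astrocytic glutamate transporter (chromosome 2, 102658659 to 102790784), was at 8274 ± 705 CPM in controls and 6979 ± 522 CPM in BPA mice (-0.25 ± 0.061). Within groups, Ahdc1 and Grik5 were lower in deeper libraries, and the slope on log2 library total gives 65.6% and 80.5% of their group differences. Of the 20 genes, 2 of them predicted, 16 were lower and 4 higher, and none passed the threshold (edgeR, adjusted p 0.518 to 0.955). The 4 higher were Fabp5, a fatty acid binding protein (chromosome 3, 10012548 to 10016607; 71.9 ± 0.864 CPM in controls and 86.9 ± 7.08 CPM in BPA mice; 0.28 ± 0.055), Pqbp1 (0.20 ± 0.047), Bag1, a co-chaperone (0.18 ± 0.043), and Srp68, part of the signal recognition particle (0.17 ± 0.041).

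The other named genes of this group were lower. R3hdm2 was at 403 ± 70.6 CPM in controls and 293 ± 14.7 CPM in BPA mice (-0.46 ± 0.098) and Pabpn1, a poly(A) binding protein, at 167 ± 28.8 CPM in controls and 120 ± 14.3 CPM in BPA mice (-0.47 ± 0.11). Nfat5, a transcription factor of osmotic stress, had a log2 fold change of -0.23 ± 0.051, Nr4a3, an inducible nuclear receptor, -0.33 ± 0.081, and Gpd1l -0.29 ± 0.075. Among weakly expressed genes, Plpp4 was at 4.79 ± 0.617 CPM in controls and 2.90 ± 0.525 CPM in BPA mice (-0.72 ± 0.14), Nme4 had a log2 fold change of -0.75 ± 0.18, Mum1l1 -0.31 ± 0.078 and Mybph -1.18 ± 0.26, the last below 1 CPM in both groups. Rtl1, an imprinted gene, had -0.61 ± 0.13 and Tor1aip1 -0.22 ± 0.044. R3hdm2, Rtl1, Mybph, Tor1aip1 and Slc1a2 overlap a gene on the opposite strand, which leaves their counts uncertain. For 15 of the 16 lower genes and all 4 higher genes the groups did not overlap; 2.79% of all tested genes had no overlap against 2.86% expected by chance.

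**Figure D1:**
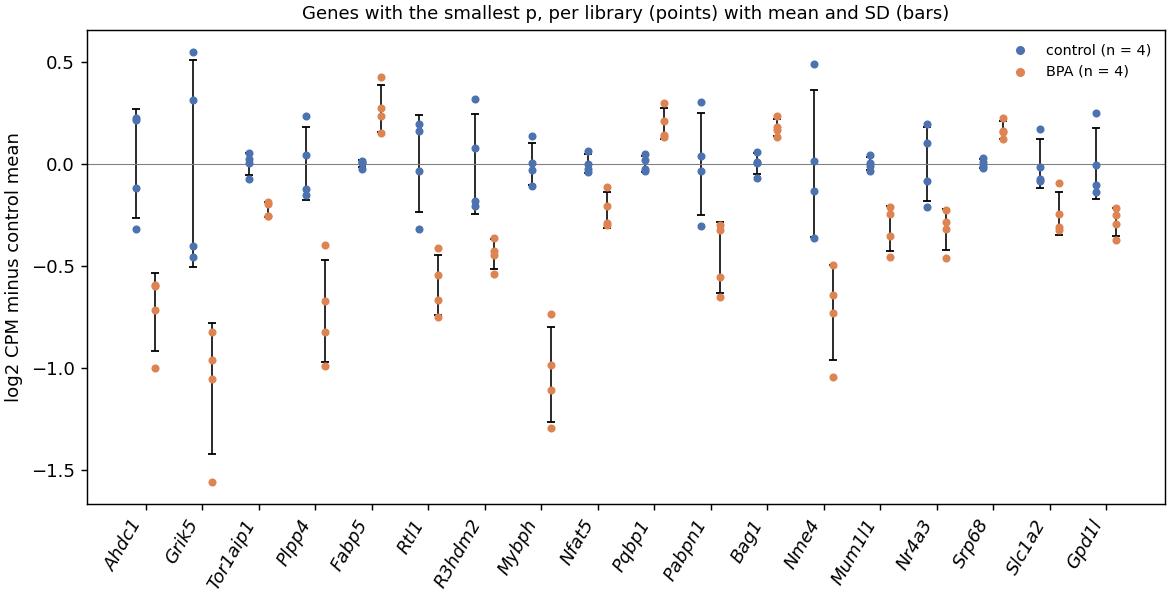
Log2 CPM minus the control mean for the 18 named genes with the smallest p; points are libraries (4 control, 4 BPA), bars are mean ± SD. The spread among controls is wide for Grik5, at 677 ± 235 CPM, and narrow for Fabp5, at 71.9 ± 0.864 CPM.

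Across the 15434 genes tested, edgeR called 0 at an adjusted p of 0.05 or 0.10, and 698 had an unadjusted p under 0.05 (343 higher and 355 lower), where 771.7 are expected by chance. That number was 354 without BPA replicate 2 and 1167 without control replicate 3. Limma-voom called 0 genes, with 952 at an unadjusted p under 0.05. DESeq2 was run without the filter on low counts and gave a p for 20749 genes, so its counts have a different base. It called 7 genes, with 627 at an unadjusted p under 0.05. Of the 7, Ahdc1, R3hdm2, Tor1aip1, Plpp4, Nfat5 and Gm20219 were lower and Fabp5 was higher. Gm20219, a predicted protein-coding gene (chromosome 17, 56551414 to 56554387), was at 2.84 ± 0.381 CPM in controls and 1.16 ± 0.401 CPM in BPA mice (-1.30 ± 0.22; DESeq2 adjusted p 0.000812) and was chosen after its values were seen. DESeq2 called 20, 15, 22 and 2 genes without control replicate 1, 2, 3 and 4, and 3, 2, 3 and 2 without BPA replicate 1, 2, 3 and 4. With log2 library total as a covariate it called 3, Lrp1, Malat1 and Meg3, of which 0 were among the 7.

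**Figure D2:**
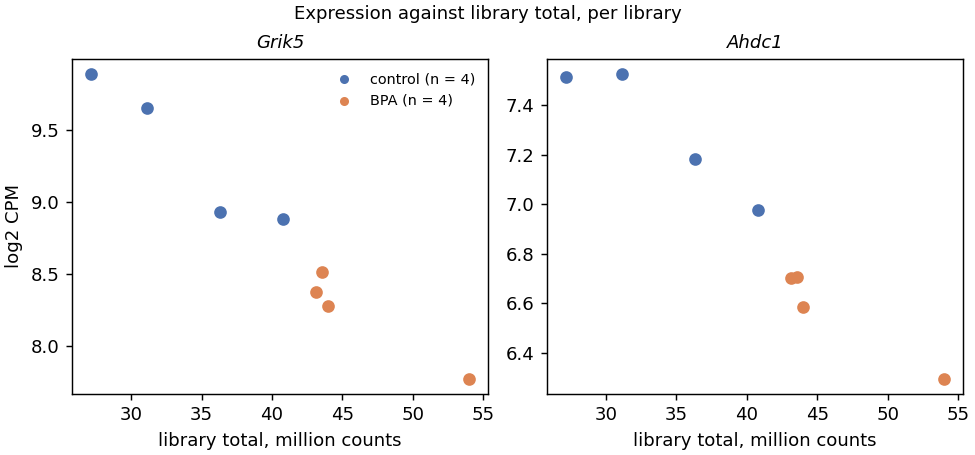
Log2 CPM of Grik5 and Ahdc1 (vertical axes) against library total in M counts (horizontal axes); points are libraries. The deepest library, at 54.01 M counts, has the lowest value of both genes.

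Of the enzymes of neuroactive steroid synthesis fixed in advance, none passed the test. Srd5a1, the steroid reductase that makes the precursor of allopregnanolone (chromosome 13, 69573449 to 69611442), was at 6.54 ± 0.335 CPM in controls and 6.33 ± 0.0824 CPM in BPA mice, a fold of 0.967 with a 95% interval of 0.864 to 1.08. Cyp11a1, which makes pregnenolone, had a fold of 0.997 (95% interval 0.842 to 1.18), Star, which delivers cholesterol to it, 0.995 (0.886 to 1.12), and Akr1c14 1.06 (0.793 to 1.42). Among steroid receptors, folds were 0.962 for Esr1, 0.985 for Nr3c1, the glucocorticoid receptor, and 0.984 for Nr3c2, the mineralocorticoid receptor. Fkbp5, a co-chaperone induced by glucocorticoids, was at 56.4 ± 1.13 CPM in controls and 61.7 ± 1.66 CPM in BPA mice (0.13 ± 0.041; edgeR adjusted p 0.955).

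No gene of serotonin, catecholamine or GABA function fixed in advance passed the test. Folds were 0.943 for Htr1a, 0.964 for Tph2 (95% interval 0.693 to 1.34), 1.00 for Maoa, 0.975 for Maob and 1.17 for Th (0.707 to 1.95). Htr2c, a serotonin receptor that choroid plexus also expresses, was at 62.2 ± 12.1 CPM in controls and 51.4 ± 4.90 CPM in BPA mice (-0.28 ± 0.11, or -0.14 without control replicate 2, the control library with the highest choroid plexus score). For the GABA genes, folds were 1.01 for Gad1, 0.967 for Gad2, 1.01 for Gabra4 and 1.12 for Gabrd. Stress and glial genes gave 1.02 for Bdnf, 0.946 for Ntrk2, 1.15 for Crh (0.815 to 1.61), 0.893 for Crhr1 and 0.979 for Gfap. Without control replicate 2 the log2 fold changes of Crh and Crhr1 were 0.027 and -0.057, and without control replicate 1 those of Th and Gabrd were 0.072 and 0.11. For Htr1a it was -0.084 with all libraries and -0.011 without BPA replicate 3. Of the 28 genes fixed in advance, 25 were tested and 0 passed over all genes or adjusted over the list alone (lowest adjusted p 0.188); only Fkbp5 and Htr2c had an unadjusted p under 0.05. For 23 of the 25, the 95% interval of the fold lay inside 1.5-fold. Hsd3b2, Esr2 and Slc6a4 had 23, 57 and 14 reads over all 8 libraries and were too low to test. Srd5a1, Nr3c2, Fkbp5, Gad1, Gabra4, Bdnf, Ntrk2 and Gfap overlap a gene on the opposite strand, which leaves their counts uncertain.

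**Figure D3:**
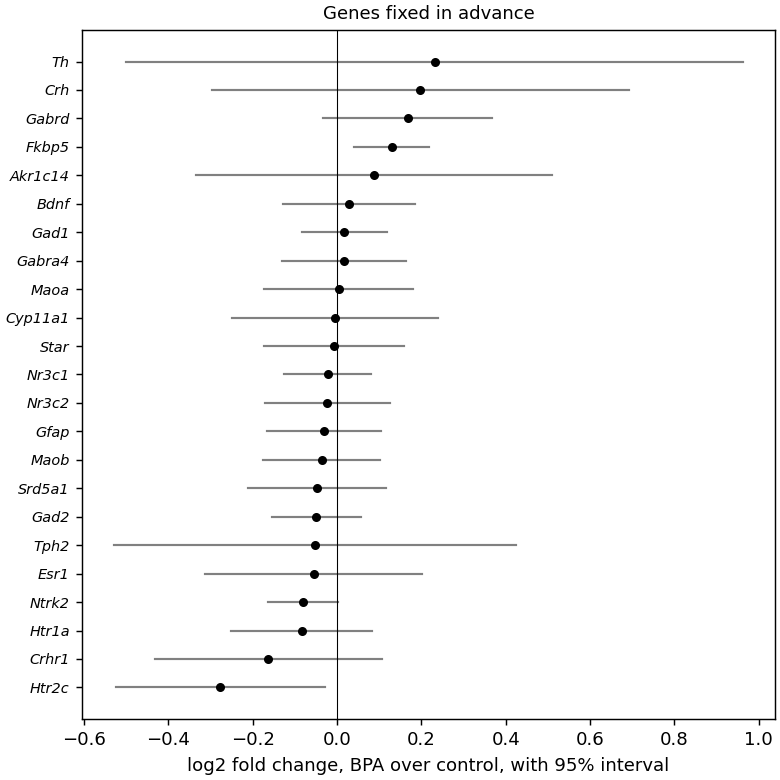
Log2 fold change of BPA over control (horizontal axis) for 23 of the 25 tested genes fixed in advance (vertical axis); points are estimates and lines are 95% intervals. Folds lie between 0.826 (Htr2c) and 1.17 (Th).

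Of the 38 gene lists tested, 7 passed camera's threshold with the preset correlation, 5 higher and 2 lower in BPA mice, and none passed with an estimated correlation. Glucocorticoid-induced genes ranked highest (median log2 fold change 0.14, 18 of 19 members higher, adjusted p 2.22e-05, and adjusted p = 0.817 with an estimated correlation), with Fkbp5 and Mt2, a metallothionein (0.37 ± 0.14, or 0.23 without BPA replicate 4), as the members with the smallest p. Dentate granule cell markers followed (median 0.15, 11 of 12 members higher, adjusted p 0.0126), with Npnt at 0.20 ± 0.094 and Calb1, a calcium buffer, at 0.11 ± 0.053. The dentate list score was 5.64 ± 0.206 in controls and 5.78 ± 0.0285 in BPA mice (exact permutation p = 0.4). No BPA score lay above the highest control score. Circadian clock genes (median 0.078, 16 of 19 members higher, adjusted p 0.0391) included Cry1 (0.21 ± 0.083) and Per2 (0.16 ± 0.094, or 0.10 without control replicate 2). Interferon response genes (median 0.072, 17 of 24 members higher, adjusted p 0.0391) included Ifit3 (0.44 ± 0.13) and Oas1a (0.83 ± 0.32), the latter below 1 CPM. Cholesterol synthesis genes (median 0.054, 19 of 23 members higher, adjusted p 0.0391) included Fdft1 (0.19 ± 0.063) and Msmo1 (0.16 ± 0.079, or 0.081 without BPA replicate 4).

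Lower in BPA mice were ependymal cell markers (median -0.31, 11 of 11 members lower, adjusted p 0.0126), among them Foxj1, a regulator of motile cilia (-0.42 ± 0.18), and Ak7 (-0.64 ± 0.32), both at -0.21 without control replicate 2, and CA3 and CA2 pyramidal neuron markers (median -0.082, 9 of 13 members lower, adjusted p 0.0391), with Cdh24 at -0.29 ± 0.11 and Nectin3 at -0.19 ± 0.072 (-0.12 without control replicate 4). No member of the 7 lists passed over all genes or adjusted over the list alone. With an estimated inter-gene correlation, 0 of the 7 held (lowest adjusted p = 0.817), and fry called 0 lists (lowest adjusted p 0.701 directional and 0.680 mixed). The glucocorticoid list stayed past camera's threshold whichever 1 library was left out (largest adjusted p 0.00846, without BPA replicate 4). Without control replicate 2 and BPA replicate 3 together, its median was 0.081 and camera's adjusted p 0.0593. Over the 21 settings with the preset correlation its median ran from 0.081 to 0.216. The largest adjusted p on leaving out 1 library was 0.546 for ependymal markers (without control replicate 2, median -0.037), 0.224 for dentate granule cells (without control replicate 1, median 0.071), 0.245 for circadian genes (without control replicate 2, median 0.048), 0.514 for interferon genes (without BPA replicate 4, median 0.0059), 0.430 for cholesterol synthesis (without BPA replicate 3, median 0.026) and 0.278 for CA3 and CA2 markers (without control replicate 4); without BPA replicate 4 the CA3 and CA2 median was 0.0020. Thinning the libraries to the smallest total left 3 lists called, as did the choroid plexus score as a covariate, and leaving out BPA replicate 3 or 4 left 3 and 2.

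**Figure D4:**
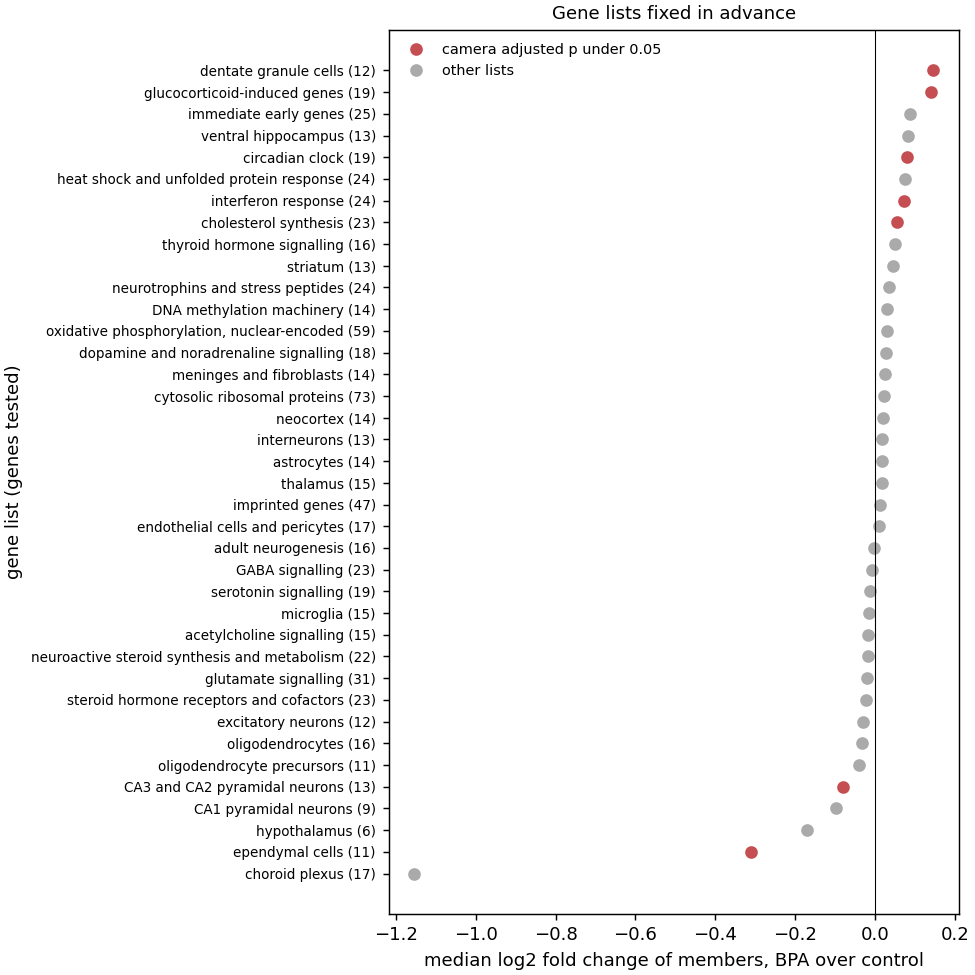
Median log2 fold change, BPA over control (horizontal axis), of the 38 lists (vertical axis, with the number of genes tested); filled red points passed camera's adjusted p of 0.05. Choroid plexus has the lowest median, at -1.15, and did not pass.

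Markers of neighbouring tissue varied between libraries. Choroid plexus markers had a median of -1.15, with 17 of 17 members lower, but did not pass (adjusted p 0.0821), and the list score was highest in control replicate 2, at 5.22 against 1.30 to 2.04 in the other controls, and in BPA replicate 3, at 3.73 against 0.675 to 2.27. Without control replicate 2 the median was 0.67. Folr1 was at -1.80 ± 0.93 (0.24 without control replicate 2) and Kl at -0.66 ± 0.35 (-0.023 without control replicate 2). Meningeal and fibroblast markers (5 of 14 members lower, adjusted p 0.778) included Slc6a13 (0.37 ± 0.44) and Slc22a6 (0.49 ± 0.63), which were at -0.32 and -0.69 without BPA replicate 3. Endothelial and pericyte markers did not pass (10 of 17 members higher, adjusted p 0.865), with Rgs5 at -0.17 ± 0.052 and Ly6c1 at 0.15 ± 0.11 (0.070 without BPA replicate 3). The ependymal score was 1.22 ± 0.488 in controls and 0.921 ± 0.324 in BPA mice (n = 4 each; exact permutation p = 0.3714), and control replicate 2 was highest for both lists, while BPA replicate 3 was highest of the BPA mice for choroid plexus and lowest of all 8 libraries for ependymal markers, at 0.705.

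**Figure D5:**
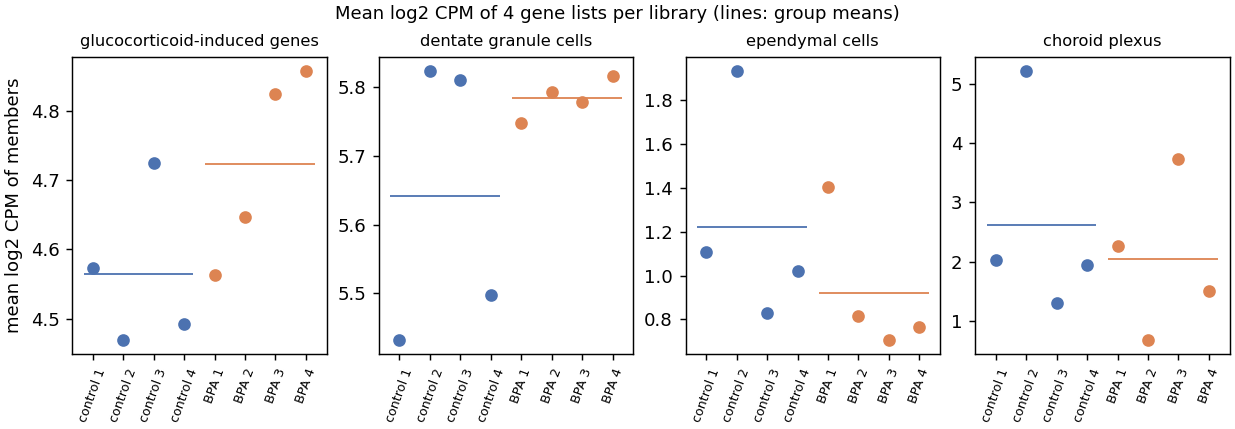
Mean log2 CPM of the members of 4 lists (vertical axes) in each library (horizontal axes); lines are group means. Control replicate 2 has the highest ependymal and choroid plexus scores, at 1.93 and 5.22.

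Neuronal and glial lists other than these did not pass. Oligodendrocyte markers (12 of 16 members lower, adjusted p 0.0642) included Ugt8a (-0.16 ± 0.054) and Ermn (-0.13 ± 0.047), and oligodendrocyte precursors (7 of 11 members lower, adjusted p 0.535) Olig1 (-0.11 ± 0.054) and Vcan (-0.071 ± 0.059). CA1 pyramidal neurons (8 of 9 members lower, adjusted p 0.168) included Pou3f1 (-0.15 ± 0.082) and Man1a (-0.13 ± 0.086), and ventral hippocampus (10 of 13 members higher, adjusted p 0.124) Calb2 (0.17 ± 0.060) and Htr2c. Excitatory neurons (7 of 12 members lower, adjusted p 0.765) had Snap25 at -0.093 ± 0.061 and Nrn1 at -0.11 ± 0.080, and interneurons (7 of 13 members higher, adjusted p 0.778) Erbb4 at -0.13 ± 0.048 and Sst at 0.13 ± 0.049. Astrocyte markers (8 of 14 members higher, adjusted p 0.869) held 1 member past the threshold adjusted over the list alone, Slc1a2, lower in BPA mice. Its edgeR adjusted p was 0.02295 over the list and 0.955 over all genes. Microglia (8 of 15 members lower, adjusted p 0.865) had Tyrobp at 0.21 ± 0.099 and Fcrls at 0.10 ± 0.084. Neighbouring brain regions were also tested: thalamus (8 of 15 members higher, adjusted p 0.778; Prkcd -0.17 ± 0.095), striatum (7 of 13 members higher, adjusted p 0.778; Six3 -1.11 ± 0.74, or 0.25 without control replicate 2, and Tac1 0.14 ± 0.10), neocortex (7 of 14 members higher, adjusted p 0.869; Ddit4l -0.18 ± 0.10 and Cux2 -0.11 ± 0.079) and hypothalamus (4 of 6 members lower, adjusted p 0.778; Nkx2-1 -0.57 ± 0.26 and Gal 0.56 ± 0.25). Single libraries moved some of these values by over 1.5 times: without control replicate 4, Snap25 was at -0.016, Nrn1 at -0.043, Man1a at -0.037 and Pou3f1 at -0.083. Nkx2-1 was at -0.35 without control replicate 2, Cux2 at -0.051 without control replicate 1, Vcan at -0.029 and Tac1 at 0.083 without BPA replicate 1, and Fcrls at 0.062 and Prkcd at -0.092 without BPA replicate 4.

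Signalling lists did not pass. Glutamate signalling (17 of 31 members lower, adjusted p 0.226) held 2 members past the threshold adjusted over the list alone, Grik5 and Slc1a2. For Grik5 the edgeR adjusted p was 0.00487 over the list and 0.721 over all genes. Immediate early genes (19 of 25 members higher, adjusted p 0.0822) held 1 such member, Nr4a3, which was lower in BPA mice (edgeR adjusted p over the list 0.0381). Imprinted genes (25 of 47 members higher, adjusted p 0.869) also held 1, Rtl1, again lower in BPA mice (edgeR adjusted p over the list 0.02245). None of these genes passed over all genes, and adjustment over a list alone does not cover the 38 lists tested. GABA signalling (11 of 23 members higher, adjusted p 0.869) had Gabbr2 at 0.10 ± 0.054, serotonin signalling (13 of 19 members lower, adjusted p 0.620) Tph1 at -2.04 ± 0.79 (0.0092 without control replicate 2), and dopamine and noradrenaline signalling (11 of 18 members higher, adjusted p 0.620) Adra2a at 0.14 ± 0.077 and Dbh at 0.53 ± 0.34 (0.84 without control replicate 2). Acetylcholine signalling (9 of 15 members lower, adjusted p 0.584) had Chrna3 at -0.36 ± 0.20 and Chrm3 at -0.10 ± 0.059. Steroid receptors and cofactors (14 of 23 members lower, adjusted p 0.355) had Fkbp5 and Paqr5 (-0.51 ± 0.24), and steroid synthesis (15 of 22 members lower, adjusted p 0.647) Cyp27a1 (-0.51 ± 0.21) and Cyp46a1 (0.067 ± 0.041). Without control replicate 2, Paqr5 was at -0.30, Adra2a at 0.065 and Cyp46a1 at 0.044, without control replicate 4 Chrm3 was at -0.053, and without BPA replicate 2 Gabbr2 was at 0.060.

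Lists of basic cell functions did not pass either. Nuclear-encoded oxidative phosphorylation (42 of 59 members higher, adjusted p 0.0642) had Atp5e at 0.24 ± 0.072 and Cox7b at 0.14 ± 0.052, and cytosolic ribosomal proteins (46 of 73 members higher, adjusted p 0.179) Rpl19 at 0.16 ± 0.044 and Rps6 at 0.15 ± 0.050. Heat shock and unfolded protein genes (18 of 24 members higher, adjusted p 0.225) had Dnajb11 at 0.14 ± 0.064 and Hspa1b at -0.30 ± 0.14 (-0.12 without control replicate 1), and thyroid hormone signalling (11 of 16 members higher, adjusted p 0.226) Thra at 0.13 ± 0.050 and Thrb at -0.093 ± 0.058 (-0.056 without control replicate 1). DNA methylation genes (9 of 14 members higher, adjusted p 0.765) had Mbd3 at 0.094 ± 0.045, adult neurogenesis (8 of 16 members higher, adjusted p 0.778) Neurod1 at 0.087 ± 0.061 (0.15 without control replicate 3), and neurotrophins and stress peptides (15 of 24 members higher, adjusted p 0.778) Sst and Ntrk2. In 10 lists the median, mean and test differed in sign, and 0 of these passed.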

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

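The tests weighed here were chosen after the result was seen, with some exceptions. Fixed in advance were the estimated correlation, fry and the fits leaving out 1 library. So were the counts of splits for genes at an unadjusted p under 0.05, for DESeq2 and for the gene lists. In each group of 4 libraries, a library stood apart when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value for 4 samples. Of 282 groups tested, 15 did, where chance alone gives about 14.1, so their number is about what chance gives.

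BPA replicate 2 had the largest total of its group, 54.01 M against 43.1 to 44.0 M (gap 0.919 of the range). BPA replicate 3 was highest for meningeal and fibroblast markers (gap 0.870; mean log2 CPM 3.78 against 2.09 to 2.31), endothelial and pericyte markers (0.865) and Npnt (0.867), and lowest for Chrna3 (0.884). BPA replicate 1 was highest for ependymal markers (0.844; 1.40 against 0.705 to 0.814) and lowest for Hspa1b (0.838). BPA replicate 2 was highest for Cyp46a1 (0.973) and lowest for Six3 (0.941). Control replicate 2 was lowest for glutamate signalling (0.922) and highest for Kl (0.838) and Crhr1 (0.893). Control replicate 4 was highest for oxidative phosphorylation (0.888) and Nectin3 (0.906). Control replicate 3 was lowest for Prkcd (0.924).

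The genes with the smallest p may follow something that goes with library depth in part. Within groups, a signed score of the 20 genes rose with log2 library total (r = 0.97, exact permutation p = 0.01042, adjusted 0.0139 over 4 relations; rho = 0.74, exact permutation p = 0.0417, adjusted 0.0556; r = 0.96 without control replicates 3 and 4), and that slope gives 42.5% of the group difference (95% interval 30.5 to 54.4%). The slope gives 80.5% (54.7 to 106.3%) for Grik5 (r = -0.96, exact permutation p = 0.00521, adjusted 0.0139; rho = -0.95, p = 0.00694, adjusted 0.0243; r = -0.94 without those libraries) and 65.6% (40.5 to 90.7%) for Ahdc1 (r = -0.95, exact permutation p = 0.01042, adjusted 0.0139; rho = -0.95, p = 0.01215, adjusted 0.0243; r = -0.98 without them). For each r without control replicates 3 and 4, deviations were still taken from the mean of all 4 controls, so these libraries still set the centre. The 95% intervals of shares, here and for the glucocorticoid list below, take the group difference as fixed. For the slopes they cover the error of the slope only. The 20 genes were also chosen for their group difference, which can lower the share that depth gives. Correcting for GC content and length kept a median 99.8% of the 20 log2 fold changes (lowest 78.4%, Nfat5). This argues against that bias for these 20 genes only. Across genes over 8 CPM, the log2 fold change did correlate with GC content (rho = 0.29) and length (rho = -0.24). Thinning all libraries to the smallest total kept 98.9% of the score difference (95% interval 97.9 to 99.8%). Thinning leaves the expected CPM as it is, so it shows only that counting more reads does not by itself give the difference. It cannot test another factor that goes with depth. A biological effect of BPA exposure stays open and cannot be told apart from depth, which separates the groups alike; the 57.5% of the score difference kept with depth as a covariate (95% interval 42.25 to 72.8%) is no support for it, as the genes were chosen for their group difference.

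Glucocorticoid-induced genes passed camera as a list, higher in BPA mice, but the call was lost with an estimated correlation (adjusted p = 0.817) and with fry (adjusted p 0.701 directional). Variation that the list's genes share between libraries is consistent with this: the list score was 4.72 ± 0.141 in BPA mice and 4.56 ± 0.115 in controls (exact permutation p = 0.1714), and the list passed camera in 15 of the 35 splits of the 8 libraries into 4 and 4. Thinning kept 98.9% of the score difference (95% interval 94.4 to 103.4%), with a list median of 0.14 (camera adjusted p 5.365e-05). As above, this shows only that counting more reads does not by itself give the difference. With log2 library total as a covariate the median was 0.17 (camera adjusted p 0.000186). These camera values rest on the preset correlation. Something that goes with depth stays open, as every BPA library was deeper than every control library and the spread is wide. The within-group slope gives -28.9% of the score difference, with a 95% interval from -228.7 to 171%. For this relation r was -0.16 (exact permutation p = 0.7031, adjusted 0.7031) and rho -0.29 (exact permutation p = 0.5503, adjusted 0.5503). Leaving control replicates 3 and 4 out after centring on all 4 controls, r was -0.27. An effect of BPA exposure remains open, as 2 of 4 BPA scores lay above the highest control score; time of day and stress at dissection were not tested, though circadian genes also passed camera, higher in BPA mice (median 0.078, adjusted p 0.0391, and adjusted p = 0.817 with an estimated correlation), and control replicate 2 had the lowest score of both lists.

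Choroid plexus and ependymal markers had medians of -1.15 and -0.31, of which only the ependymal list passed camera (adjusted p 0.0821 and 0.0126; for the ependymal list adjusted p = 0.817 with an estimated correlation), and without control replicate 2 the medians were 0.67 and -0.037. Choroid plexus tissue carried over in varying amount is consistent with the choroid part: within groups, single choroid genes followed the list score with a median correlation of 0.984 over 17 genes, and the within-group SD of the score, 1.55, exceeded the group difference of -0.581. Each gene is part of the score it was compared with, so this correlation does not separate carried-over tissue from another cause of joint variation. Of the abundant choroid plexus members, Ttr was at 470 ± 828 CPM in controls and 140 ± 172 CPM in BPA mice. Enpp2, which oligodendrocytes also express, was at 400 ± 477 and 199.9 ± 99.3 CPM. For ependymal markers the choroid plexus score as a covariate kept 55.2% of the median log2 fold change (adjusted p 0.0557), and without the choroid-rich libraries, control replicate 2 and BPA replicate 3, the median was -0.052 (adjusted p 0.968), while BPA replicate 3, rich in choroid plexus markers, had the lowest ependymal score, 0.705; together these do not decide whether ependymal cells came with that tissue. An effect of BPA exposure on choroid plexus stays open (exact permutation p = 0.6286 for the score).

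For edgeR's count of 0 genes the splits decide nothing, since all 35 splits of the libraries into 4 and 4 give at least 0 (highest of the other splits 0). Chance can not be excluded for the other counts of calls. Of the 35 splits, the real one included, 16 gave at least 698 genes at an unadjusted p under 0.05 (highest other 2001), 13 gave at least 7 DESeq2 genes (highest other 122), and 19 gave at least 7 gene lists (highest other 15). The split with 122 DESeq2 genes set control replicates 1, 2 and 4 with BPA replicate 3 against the rest, and edgeR called 0 genes in it. Control replicate 2 and BPA replicate 3 are the choroid-rich libraries. The split was picked for its high count, and whether it reflects a structure of the samples other than the groups was not tested.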

How the results depend on the processing

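The log2 library total, thinning, GC and length offsets, choroid plexus score, removal of Rn45s and removal of the choroid-rich libraries were chosen after seeing the data. edgeR called 0 genes under every edgeR setting run and limma-voom called 0, while DESeq2 called 7. Genes at an unadjusted p under 0.05 numbered 354 (without BPA replicate 2) to 1167 (without control replicate 3) on leaving out 1 library, against 698. The 343 higher and 355 lower of these became 382 and 278 with library totals only, 306 and 392 without Rn45s, and 189 and 334 with log2 library total as a covariate. Of 38 lists, 7 were called with all libraries and 2 (without BPA replicate 4) to 9 on leaving out 1 library, with 3 without BPA replicate 3; 10 were called with log2 library total as a covariate, 9 with 1 surrogate variable and 9 with library totals only, 3 were called after thinning and 3 with the choroid plexus score as a covariate, and 0 with an estimated correlation or either fry test. The glucocorticoid list was called in 20 of 21 settings with the preset correlation (adjusted p 0.0593 without the choroid-rich libraries), dentate granule cells in 17, ependymal cells in 16, cholesterol synthesis and interferon in 12 each, circadian in 11 and CA3 and CA2 in 9. Of the lists not called with all libraries, choroid plexus was called in 6 settings (lowest adjusted p 2.34e-05), oligodendrocytes and immediate early genes in 5 each, oxidative phosphorylation in 4 (lowest adjusted p 0.00016), ribosomal proteins in 3 and 7 others in 1 or 2 each. GC and length offsets left 5 lists called. The causes of these changes were not tested, except that thinning lowers the depth and leaving out libraries lowers the sample number.

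The replicate block gave 0 genes, 498 at an unadjusted p under 0.05 and 8 lists. Deviations of same-numbered libraries had correlations of -0.12, -0.37, -0.30 and 0.070, and no BPA library correlated best with its own number. This gives no sign that the numbers pair the animals, though a weaker pairing could be missed.

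Of the log2 fold changes of named genes over the settings, DESeq2 with all libraries among them, 2335 kept their direction and side of the threshold, 7 passed it (all with DESeq2) and 65 turned sign. With DESeq2 on leaving out 1 library, Grik5, Gpd1l, Nr4a3, Pabpn1, Slc1a2, Rtl1, Bag1 and Rpl19 also passed in at least 1 fit. Sign turned with library totals only for Cyp11a1 (0.0011), with the replicate block for Maoa (-0.00085), with 1 surrogate variable for Nr3c2 (0.012) and Maoa (-0.023), and after thinning for Cyp11a1 (0.0044) and Tph2 (0.11). With GC and length offsets it turned for Nr3c1 (0.0095), and with limma-voom for Slc6a13 (-0.14), Slc22a6 (-0.26), Nr3c2 (0.0027), Tph2 (0.028) and Maoa (-0.027). With log2 library total as a covariate it turned for Man1a (0.022), Snap25 (0.069), Nrn1 (0.16), Slc22a6 (-0.083), Fcrls (-0.022), Nr3c1 (0.020), Nr3c2 (0.087), Gad2 (0.053) and the CA3 and CA2 median (0.019). With the choroid plexus score it turned for Cyp11a1 (0.035), Tph2 (0.016) and the choroid plexus median (0.021). The choroid plexus median is no test there, as the covariate is the mean of the same genes. Without the choroid-rich libraries it turned for Tph1 (0.029), Six3 (0.082), Slc6a13 (-0.26), Slc22a6 (-0.59), Star (0.045), Bdnf (-0.072), Tph2 (0.20), Maoa (-0.055), Maob (0.0067), Gad1 (-0.0042), Gabra4 (-0.029), Crhr1 (0.0017) and the immediate early gene median (-0.049).

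Leaving out 1 library, values ranged across 0 for Akr1c14 (-0.025 to 0.21), Bdnf (-0.027 to 0.078), Cyp11a1 (-0.076 to 0.053), Folr1 (-3.12 to 0.24), Gabra4 (-0.037 to 0.055), Gad1 (-0.00023 to 0.043), Gfap (-0.069 to 0.032), Maoa (-0.083 to 0.051), Maob (-0.084 to 0.00018), Nr3c1 (-0.045 to 0.0087), Nr3c2 (-0.059 to 0.030), Six3 (-1.50 to 0.25), Slc22a6 (-0.69 to 0.89), Slc6a13 (-0.32 to 0.68), Star (-0.055 to 0.028), Tph1 (-2.38 to 0.0092) and Tph2 (-0.17 to 0.14), and for the medians of CA3 and CA2 (-0.13 to 0.0020) and choroid plexus (-1.81 to 0.67).

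The medians named so far are of the 11 lists with a camera adjusted p under 0.10. Of the other 27 lists, medians turned sign for 16 with log2 library total as a covariate, 7 without the choroid-rich libraries, 6 with 1 surrogate variable, 5 after thinning, 3 with GC and length offsets, 3 with CPM over 1 in 4 libraries, 2 without the filter, 2 with the choroid plexus score, 1 with library totals only and 13 on leaving out 1 library. Of these, 3 passed after turning, all with log2 library total as a covariate: meninges and fibroblasts (0.025 to -0.43), neocortex (0.019 to -0.14) and endothelial cells and pericytes (0.0098 to -0.063).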

Other observations

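Of the 38 list scores, 1 separated all BPA from all control libraries, steroid hormone receptors and cofactors, which was lower in every BPA library (mean log2 CPM 5.51 ± 0.0154 in BPA mice and 5.55 ± 0.0195 in controls, n = 4 each; exact permutation p = 0.02857, the smallest possible; lowest adjusted p over the 38 scores 0.835). Chance gives 1.09 such lists among 38.

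The first principal component held 32.6% of the variance, with control replicate 2 at -28.9 and BPA replicate 3 at -14.7, the libraries with the highest choroid plexus score in their groups. Across genes over 8 CPM, the log2 fold change correlated with GC content (rho = 0.29) and with transcript length (rho = -0.24); genes are not independent replicates.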
